A study of Mus musculus with 3 samples.

How the data were processed

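Primary mouse peritoneal macrophages were sequenced in 3 libraries, 1 each for no treatment, apoptotic cells and LPS, and each library has a deposited table of 1 value for each of 20574 gene symbols. Groups, doses and times come from the sample labels. The values were taken as FPKM, fragments per kilobase of transcript and per 1000000 mapped fragments: the labels give no unit, but the submitters' processing notes name Cufflinks, and the smallest steps of the deposited values depend on transcript length as FPKM does. The submitters' processing notes name cutadapt 1.14, TopHat2 2.1.0, Cufflinks 2.2.1 and Cuffdiff, with the mouse build mm10. Their options and the annotation are not given in the sources used here, nor is the library's strandedness, so reads of overlapping antisense genes and of near-identical copies, such as those of ribosomal protein genes, may not be separated.

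Depth is not stated. It was estimated from the steps between the smallest values of genes with 1 annotated transcript, which are close to whole multiples of 1 read's worth. The steps were 0.295, 0.315 and 0.340 FPKM per read on 1 kb in the untreated, apoptotic-cell and LPS libraries. Length was counted after a fitted offset of 225, 200 and 175 bases was taken off. Only 36.1% to 51.6% of the ratios between libraries of genes under 1 FPKM fell within 1.5% of a ratio of small whole numbers, so reads were not recovered and no count test was run. Any error statement from these depths covers counting error only.

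Ratios were computed as log2((FPKM + 1) / (FPKM + 1)), which understates the differences of low genes, for genes with a mean of at least 1 FPKM over the 3 libraries (7147 genes). Differences of at least 2-fold on that scale were counted in each direction, as a description of these libraries. The groups, the scale, the filter, the thresholds, the gene lists, the naming rule and most alternatives were set before the data were examined. The plan took a listed 0 as a value. Because abundant housekeeping genes were also listed at 0, ratios were instead restricted to genes above 0 in both libraries. That restriction was chosen after the values were seen, and the counts as planned are printed beside it.

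Each of 38 gene lists, 28 of pathways and controls and 10 of cell type markers, was summarised by its median log2 ratio with a distribution-free binomial 95% interval over its genes. Each median was placed among those of 10000 random lists of the same size matched on deciles of mean expression. Lists with at least 5 members above 0 in both libraries were placed, and a percentile at or under 2.5 or at or over 97.5 is called apart. Older symbols were matched through the synonym table of the mouse reference, and 98.0% of the symbols had a transcript length in GENCODE M21, which also gave the mm10 coordinates. Lists with fewer members have counts only. In addition to those described in the report, NRF2 targets had 4 members above 0 in both libraries in each comparison and replication-dependent histones had 3. NK cell markers had 1 and the erythroid list 0.

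The genes named in the text are taken from the 10 largest ratios in each direction for both main comparisons and the 5 largest for apoptotic cells against LPS, leaving out small RNAs and uncharacterised models, from up to 4 members per list, and from a set of genes tied to the study's question. As planned, with 0 as a value, the ranking gave mostly ribosomal protein genes listed at 0. The ranking among genes above 0 in both libraries was added after the values were seen, as were other genes given for their values, among them members listed at 0, the examples in the plots and the genes of the shared response. Of the genes always to be named, Abca1, Mertk and Hif1a were not analysed here. Acod1 was present under its older symbol Irg1, listed at 13.1 FPKM with apoptotic cells and at 0 in both other libraries.

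Shared responses were counted over genes above 0 in all 3 libraries, beside the product of the list sizes over the number of genes and beside 200 simulations of unchanged libraries with counting error and 1 shared control. Alternatives were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 FPKM, fold thresholds of 1.5 and 4, rescaling to a sum of 1000000, median-of-ratios and upper-quartile scaling, the planned handling with a listed 0 as a value and, added later, genes above 0 in all 3 libraries. A list median under an alternative counts as unchanged inside its binomial interval or, for lists too small for an interval, within 0.3 log2 of the reported value. The steps were tested on simulated data drawn at the mean level of each gene. All simulated libraries had 1 common depth close to the estimated ones, not the depth of each library. With 200 of 7147 genes changed and counting error only, 3 repeats of the same simulation recovered 95.5%, 95.0% and 95.0% of 4-fold changes. They recovered 29.0%, 31.5% and 32.5% of 2-fold changes. A 2-fold change lies at the threshold itself and the added 1 FPKM shrinks it. Low recovery of such changes is therefore set by the threshold and does not measure depth. The list step was tested on normally distributed ratios with fewer random lists than in the report. Of 200 unchanged lists 5.5% were called apart. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.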

Results

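RNA was sequenced from primary mouse peritoneal macrophages in 3 conditions, with 1 library per condition. The macrophages were untreated, kept with apoptotic cells for 5 h at 5 apoptotic cells per macrophage, or treated for 5 h with 100 ng/ml of LPS, a bacterial lipid that sets off inflammatory signalling. Cells that had not been taken up were washed away before the RNA was collected. The series title ties the uptake of apoptotic cells, called efferocytosis, to fatty acid oxidation, the electron transport chain and the turn of macrophages towards tissue repair. The values are FPKM for 20574 gene symbols per library, summing to 199881 in the untreated library, 197222 with apoptotic cells and 200224 with LPS. The size of the smallest steps between values implies that 1 FPKM on 2 kb of transcript stands for 6.78, 6.35 and 5.88 reads in the same order. That length is counted after a fitted offset of 225, 200 and 175 bases is taken off, so a transcript of 2 kb in all holds somewhat fewer. There are no replicates, so every difference given here is between libraries, with no p-value.

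Many values were listed as exactly 0. Of the genes above 0 in both other libraries, 38.6% were listed at 0 in the untreated library, 18.6% with apoptotic cells and 21.9% with LPS. Abundant genes were among them. Eef1a1, the elongation factor that brings transfer RNA to the ribosome, was listed at 5641 FPKM in the untreated library and at 0 in the other libraries. Ppia was listed at 1841, 0 and 1767 FPKM in the untreated, apoptotic-cell and LPS libraries, and Rplp0 at 1967, 1268 and 0. A 0 in these values can be a failed estimate, so ratios were formed only for genes above 0 in both libraries compared, and a gene at 0 is reported as listed at 0.

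The first comparison sets apoptotic cells against no treatment. The labels give 5 h for both treated libraries and no time for the untreated library. An effect of treatment therefore cannot be told apart from one of time or handling in either comparison with the untreated library. Arg1, the arginase that splits arginine into ornithine and urea, stood at 344 FPKM with apoptotic cells and 13.7 FPKM without, a log2 ratio of 4.55 on the log2(FPKM + 1) scale. Ptgs2, the inducible prostaglandin synthase, stood at 3.67 against 218 FPKM (log2 ratio -5.55), and the inflammatory cytokine gene Tnf at 1.30 against 54.6 FPKM (-4.59). Among genes above 0 in both libraries, cytokine, NF-kB and immediate-early genes were lower with apoptotic cells, whereas genes of alternative activation, engulfment, sterol synthesis and the lysosome were higher. With a listed 0 taken as a value, as planned, only the cytokine list of these stayed apart from random lists. In mm10, Arg1 lies on chromosome 10 from 24915221 to 24927484, Ptgs2 on chromosome 1 from 150100031 to 150108227 and Tnf on chromosome 17 from 35199381 to 35202007.

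The inflammatory cytokine and chemokine list had the lowest median of the lists in this comparison, at -2.40 (95% interval over its genes -4.59 to -1.68), below every random list of the same size and expression level (percentile 0). Of its 9 members above 0 in both libraries, 8 were at least 2-fold lower with apoptotic cells and 0 were higher. Besides Ptgs2 and Tnf they included the monocyte-attracting chemokine genes Ccl2, at 11.2 against 107 FPKM (-3.15), and Ccl7, at 6.88 against 41.3 FPKM (-2.42). Another 10 members had a listed 0. Il1b was listed at 11.2 FPKM with apoptotic cells and at 0 in the untreated library, and Il6 at 0.648 and 0. Il12b and Ifnb1 were listed at 0 in every library. The list of NF-kB targets and feedback regulators had a median of -1.62 over 5 members (percentile 0.39), with Socs3 at 10.2 against 42.0 FPKM and Nfkbia at 23.8 against 85.8 FPKM. With a listed 0 taken as a value, as planned, that median was 0.37 (percentile 64.9), and 9 of its 14 members had a 0. Immediate-early genes had a median of -1.33 (interval -2.07 to 0.79, percentile 0): 6 of 11 were at least 2-fold lower, among them Egr1 (-2.16) and Btg2 (-2.07), while Fos was higher (1.66). Antigen presentation genes had a median of -1.20 over 5 members (percentile 0.41), with the peptide transporter gene Tap1 at 13.3 against 40.2 FPKM. These 5 were Tap1, Tap2, Tapbp, Psmb8 and Psmb9, and the other 4 of 9 were listed at 0 in the untreated library. With apoptotic cells H2-Ab1 was listed at 307 FPKM, H2-DMb1 at 8.46 FPKM, Cd83 at 8.30 FPKM and H2-Aa at 0. The median therefore does not stand for antigen presentation as a whole. Interferon-stimulated genes did not stand apart (median -0.42, percentile 22.4).

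Genes of alternative activation and tissue repair had a median of 1.53 (interval -0.68 to 2.79, percentile 100), with 6 of 10 members at least 2-fold higher and 1 lower. After Arg1, the largest were Spp1, which encodes osteopontin (446 against 63.6 FPKM, 2.79), and the alternative-activation markers Chi3l3 (20.1 against 3.77 FPKM, 2.14) and Clec10a (9.78 against 1.67 FPKM, 2.01). The lower member was the angiogenic factor gene Vegfa, at 11.0 against 24.7 FPKM. Il10, the anti-inflammatory cytokine gene on chromosome 1, was listed at 5.01 FPKM with apoptotic cells, 17.1 FPKM with LPS and 0 in the untreated library. Receptors, bridging molecules and other engulfment genes had a median of 1.46 (interval 0.46 to 2.63, percentile 99.9), with 6 of 9 at least 2-fold higher and 0 lower. They included the complement gene C1qa (544 against 59.4 FPKM, 3.18), the integrin gene Itgb5 (2.63), and Pros1 (2.56) and Mfge8 (48.1 against 7.70 FPKM), whose products bridge dying cells to phagocytes. The receptor gene Axl was listed at 38.8 FPKM in the untreated library and at 0 with apoptotic cells.

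Sterol synthesis genes had a median of 0.92 (interval 0.03 to 1.49, percentile 99.7), with 4 of 10 at least 2-fold higher and 0 lower, led by Sc4mol (1.72), Fdps (1.49) and Mvd (1.29). Lysosome genes had a median of 1.12 over 5 members (percentile 98), with Atp6v0d2, a subunit of the acidifying proton pump, at 19.2 against 2.08 FPKM. That percentile was no longer outside the random range with a pseudocount of 0.1 or with each library rescaled to a common sum. Fatty acid oxidation genes had a median of 0.33 (interval 0.10 to 0.74), at percentile 91.9 and so not apart from random lists. Of 13 members, 2 were at least 2-fold higher, Echs1 (133 against 31.1 FPKM, 2.07) and Decr1 (1.11), 0 were lower and 11 differed by less than 2-fold. Cpt1a, the gate of fatty acid entry into mitochondria, was listed at 9.78 FPKM in the untreated library and at 0 with apoptotic cells. Cpt2 stood at 5.94 against 5.13 FPKM. Nuclear genes for complex I had a median of 0.62 (interval 0.38 to 0.76, percentile 94.3), with 3 of 15 at least 2-fold higher, Ndufb4 (1.23), Ndufs6 (1.20) and Ndufa1 (1.12), and 0 lower.

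Medians were 0.56 for complexes II to IV (percentile 82.5), 0.39 for ATP synthase (50.9), 0.10 for the TCA cycle (50.1) and 0.69 for glycolysis (81.9), where the lactate dehydrogenase gene Ldha stood at 825 against 276 FPKM (1.58). None of the 13 mitochondrially encoded genes on the list was analysed here. The LXR and sterol efflux list went both ways around a median of 0.11 (percentile 66.4): Apoc1 was higher (281 against 29.0 FPKM, 3.23), while the sterol exporter gene Abcg1 was lower (5.18 against 14.9 FPKM, -1.37). Lipid uptake and storage genes had a median of 0.58 over 5 members (percentile 87.3), with the cholesteryl ester hydrolase gene Nceh1 at 100.2 against 15.0 FPKM (2.66). Stress-response genes (median -0.43, percentile 3.02) had 4 of 9 members at least 2-fold lower, among them Chac1 (-2.82), Trib3 (-2.11) and Atf4 (-1.90), and 2 higher. Hypoxia genes had a median of -0.31 (percentile 19.3), with Adm (-4.19) and Ddit4 (-3.08) lowest, cell cycle genes of -0.60 (8.33) and housekeeping genes of 0.39 (68.3). Cytosolic ribosomal protein genes lay low as a group, with a median of -0.63 (interval -0.93 to -0.43, percentile 0.065) and 2 of 15 at least 2-fold lower, Rpl3 (-1.06) and Rpl5 (-1.05).

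By the fixed naming rule applied to genes above 0 in both libraries, the largest positive ratios with apoptotic cells were those of Tmem37 (54.5 against 1.25 FPKM, 4.62), Arg1, the immunoglobulin receptor gene Fcgr4 (3.26), Tspan4 (3.26), Apoc1, Wnt2 (3.23), Lrg1 (3.21), C1qa, Sepp1 (3.16) and the complement receptor gene C5ar1 (3.15). The most negative were those of Ptgs2, Tnf, Adm, the B-cell chemokine receptor gene Cxcr5 (12.1 against 214 FPKM, -4.03), N4bp3 (-3.87), Rgs16 (-3.84), Bcar3 (-3.84), Xist (-3.74), the B-lineage gene Ly6d (42.7 against 563 FPKM, -3.69) and Cxcl5 (-3.46). Taking a 0 as a value, the same rule ranked mostly ribosomal protein and translation genes, with Rpl10, Gnb2l1 and Rps18 at the top, listed at 1335, 1076 and 1054 FPKM with apoptotic cells and at 0 in the untreated library, and Eef1a1 and Rpl38 at the bottom.

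Markers of other peritoneal cells differed between these libraries too. The mast cell and eosinophil list had a median of -2.20 (interval -2.57 to -0.56, percentile 0): the tryptase gene Tpsb2 stood at 4.72 FPKM with apoptotic cells and 23.8 FPKM without, and Mcpt4 at 1.81 and 15.7 FPKM. The mesothelial and fibroblast genes Dcn (1.47 against 11.4 FPKM) and Col1a1 (0.0802 against 4.47 FPKM) and the dendritic cell gene Kmo (0.140 against 5.45 FPKM) were lower as well. The B-cell genes Blnk (38.4 against 82.7 FPKM) and Cr2 (0.0965 against 3.44 FPKM) were the only 2 of 11 B-cell markers above 0 in both libraries. T cell and thymocyte genes had a median of -0.23 over 5 members (percentile 47.8), but Rag1, the recombinase gene of developing lymphocytes, was listed at 41.2 FPKM with apoptotic cells and at 0 in the untreated library. The neutrophil list had a median of 1.26 over 5 members (percentile 99.5, but 80.6 with a listed 0 taken as a value). In it 3 members were at least 2-fold higher, Mmp8 (2.29), Lcn2 (1.53) and S100a8 (1.26), while S100a9 (0.07) and Camp (0.03) were level. Of the large peritoneal macrophage markers, 3 of 3 above 0 in both libraries were at least 2-fold higher, Cxcl13 (364 against 44.7 FPKM), Naip1 (2.13) and Cd9 (1.35). Another 7 had a listed 0. Lyz1 (349 FPKM), F5 (29.6 FPKM), Alox15 (12.3 FPKM), Vsig4 and Timd4 were above 0 in the untreated library and listed at 0 with apoptotic cells. Gata6 and Tgfb2 were listed at 0 in both. The marker differences run alongside the lower cytokine, immediate-early and ribosomal genes and the higher engulfment genes described above.

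In total 3369 genes were above 0 in both libraries, of which 418 were at least 2-fold higher and 554 at least 2-fold lower with apoptotic cells, around a median log2 ratio of -0.13. Median-of-ratios scaling moved that median by 0.04 and upper-quartile scaling by 0.23. Relative to the median of all genes, list medians were -2.27 for cytokines, 1.67 for repair, 1.60 for engulfment and -0.50 for ribosomal proteins. Counting error alone gave a median of 11 and 12 such genes in 200 simulations. Of 25 lists with at least 5 members above 0 in both, 5 lay above and 6 below the central 95% of random lists, where 5% fall outside by chance. Among the lists too small to place, NRF2 targets had 2 of 4 members at least 2-fold higher and 1 lower, histones 0 of 3 and 2, and NK cell markers 0 of 1 and 1. With a listed 0 taken as a value, 2682 genes were higher and 1378 lower, of which 2264 and 824 rest on a 0, and of the lists named above as apart only the cytokine, ribosomal protein and mast cell lists remained so.

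**Figure D1:**
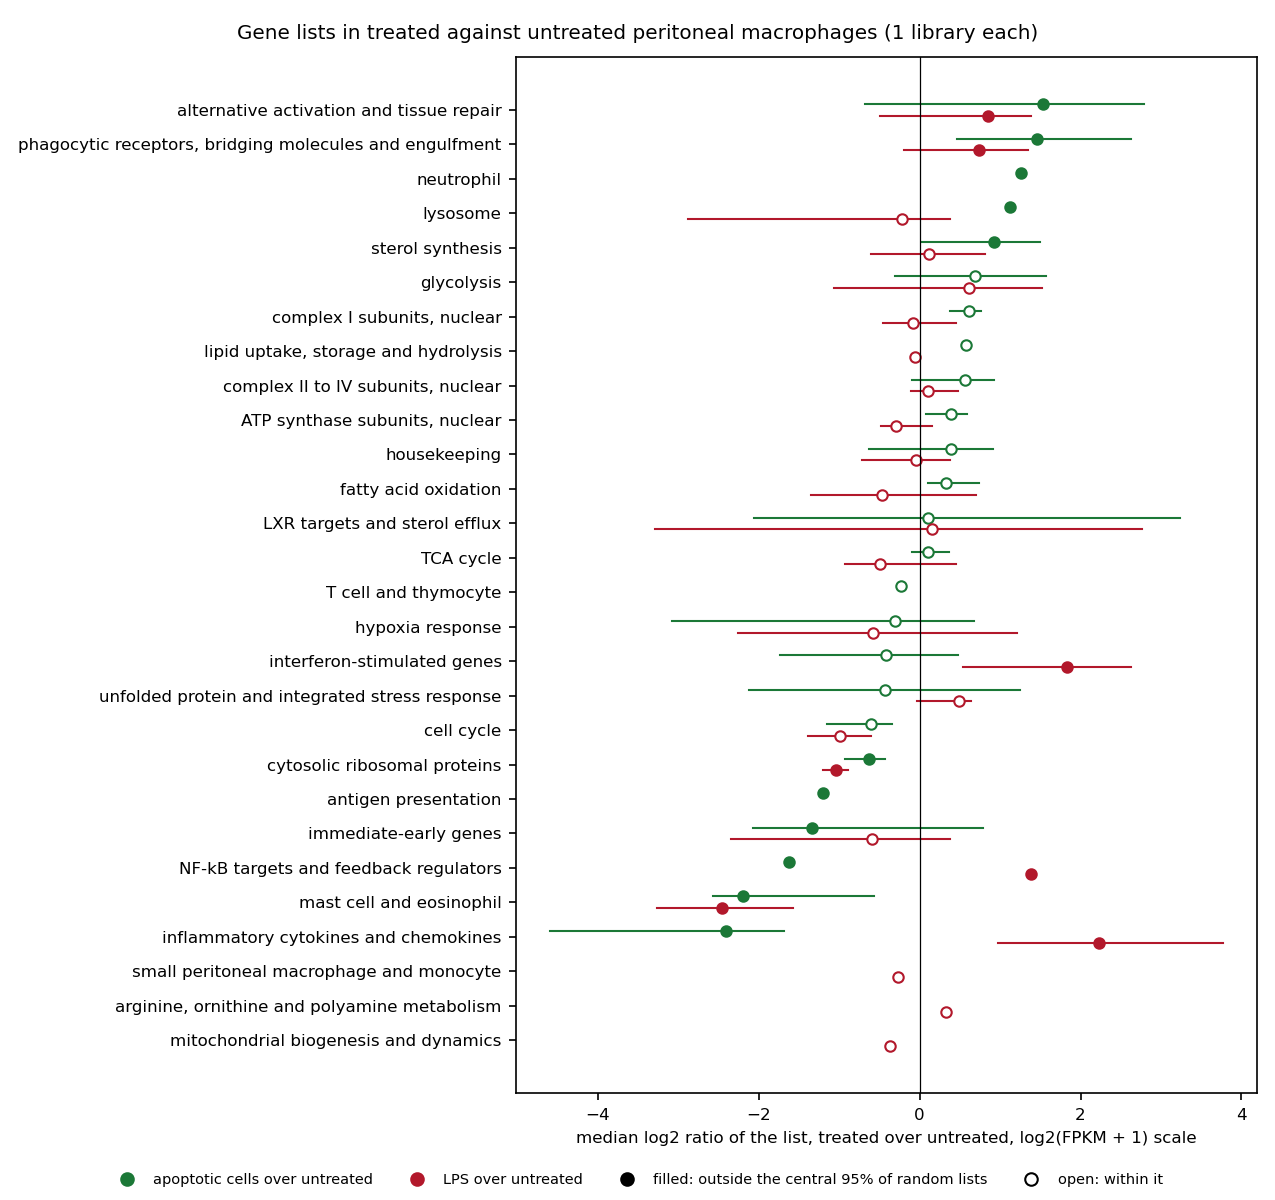
Median log2 ratio of each gene list (horizontal axis, log2(FPKM + 1) scale) with apoptotic cells (green) and LPS (red) over the untreated library, with lines for the 95% interval over the genes of lists large enough to give one. Filled points lie outside the central 95% of random lists; the cytokine list sits at -2.40 with apoptotic cells and at 2.23 with LPS.

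The second comparison sets LPS against no treatment, as an inflammatory counterpart to efferocytosis. Il1b, which encodes interleukin 1 beta and lies on chromosome 2 from 129364570 to 129371139, was listed at 11441 FPKM with LPS, 5.71% of all FPKM in that library, and at 0 in the untreated library. Tnf stood at 264 against 54.6 FPKM (log2 ratio 2.25), and the chemokine gene Ccl5 at 1353 against 292 FPKM (2.21). Cytokine, interferon-stimulated and NF-kB genes were higher with LPS, and ribosomal protein genes were lower. The median log2 ratio of all genes was -0.40, so list medians are also given relative to it.

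The cytokine and chemokine list had a median of 2.23 (interval 0.98 to 3.77, percentile 100), or 2.64 relative to all genes. Of 8 members above 0 in both libraries 7 were at least 2-fold higher and 0 lower, with the growth factor gene Csf2 (92.6 against 5.84 FPKM, 3.77), Il23a (3.08) and Cxcl10 (2.86) ahead. Another 11 members had a listed 0, among them Ptgs2, listed at 0 with LPS, and Ccl2. Interferon-stimulated genes had a median of 1.83 (interval 0.54 to 2.63, percentile 100), or 2.24 relative to all genes. Of 8 members 6 were at least 2-fold higher and 0 lower, led by Ifit1 (2.63), Gbp2 (2.61) and Oas3 (2.17). NF-kB targets had a median of 1.38 over 5 members (percentile 99.8), or 1.78 relative to all genes, with Socs3 (225 against 42.0 FPKM, 2.40) and Irak3 (1.93) highest. Nos2, the inducible nitric oxide synthase gene, was listed at 1.76 FPKM with LPS and 0.442 FPKM without.

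Repair and engulfment genes were also higher with LPS than without treatment. The alternative activation and repair list had a median of 0.85 (interval -0.49 to 1.38, percentile 99.95), or 1.26 relative to all genes, with 5 of 12 members at least 2-fold higher. The epidermal growth factor family genes Areg (79.1 against 3.47 FPKM, 4.16) and Hbegf (2.58) led it, followed by Mmp9 (1.38) and Spp1 (1.26), while Gpnmb was lower (-1.01) and Arg1 stood at 19.1 against 13.7 FPKM (0.45). The engulfment list had a median of 0.74 (interval -0.19 to 1.35, percentile 99.7). Of its 10 members 4 were at least 2-fold higher and 0 lower, C1qa (1.80), Mfge8 (1.35), Pros1 (1.29) and Timd4 (1.03). That placement was lost when only genes with a mean of at least 5 FPKM were kept (percentile 71.4).

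Energy and lipid lists did not stand apart with LPS. Fatty acid oxidation genes had a median of -0.46 (percentile 37.6), or -0.06 relative to all genes: of 11 members 1 was at least 2-fold higher, Acsl4 (1.53), and 2 were lower, Eci1 (-1.40) and Acaa2 (-1.35). Cpt1a stood at 4.63 against 9.78 FPKM (-0.94) and Cpt2 at 4.81 against 5.13 FPKM (-0.08). Medians relative to all genes were 0.32 for complex I (percentile 30.1), 0.51 for complexes II to IV (52.9), 0.11 for ATP synthase (8.19) and -0.09 for the TCA cycle (11.3). Glycolysis genes lay 1.02 above the median of all genes (percentile 91.0), with the glucose transporter gene Slc2a1 at 139 against 48.0 FPKM (1.52) and Tpi1 at 30.2 against 64.3 FPKM (-1.06). Other medians, as ratios to the untreated library, were 0.15 for LXR targets and sterol efflux (percentile 89.5), 0.12 for sterol synthesis (89.7), -0.05 for lipid uptake and storage (55.9), -0.21 for the lysosome (53.8), -0.37 for mitochondrial biogenesis and dynamics (48.6), 0.50 for the unfolded protein and integrated stress response (94.3), -0.58 for hypoxia (24.3), -0.60 for immediate-early genes (6.32), -0.98 for the cell cycle (8.08, but 1.95 with a pseudocount of 0.1) and -0.04 for housekeeping genes (37.2). Among LXR targets, Abcg1 was at 0.630 against 14.9 FPKM (-3.29), and Ch25h, whose enzyme makes 25-hydroxycholesterol, at 47.5 against 6.16 FPKM (2.76).

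Ribosomal protein genes had a median of -1.03 (interval -1.21 to -0.89, percentile 0.03), or -0.63 relative to all genes, with 8 of 15 at least 2-fold lower, led by Rpl3 (-1.53) and Rpl32 (-1.42). Mast cell markers were again lower than in the untreated library. The mast cell and eosinophil list had a median of -2.46 (interval -3.26 to -1.57, percentile 0), with 6 of 6 members at least 2-fold lower. The T-cell genes Thy1 (0.219 against 15.0 FPKM) and Dntt (0.160 against 13.5 FPKM) and the B-cell gene Blnk (18.5 against 82.7 FPKM) were lower too. Neutrophil markers went both ways, with S100a8 (222 against 48.1 FPKM, 2.18) and Lcn2 (272 against 64.1 FPKM, 2.07) higher, Mmp8 lower (-1.17) and Camp under 2-fold. Large peritoneal macrophage markers above 0 in both libraries numbered 4, of which 2 were at least 2-fold higher, Cxcl13 (1.31) and Timd4. Another 6 had a listed 0. The small peritoneal macrophage and monocyte list had a median of -0.27 over 5 members (percentile 62.0).

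By the naming rule among genes above 0 in both libraries, the largest positive ratios with LPS were those of Areg, its relative Ereg (4.14), the hyaluronan synthase gene Has1 (3.82), Csf2, the nicotinic acid receptor gene Niacr1 (3.37), Csrp2 (3.25), Oas1g (3.22), Prok2 (3.10), Arg2 (66.8 against 6.94 FPKM, 3.09) and Il23a. The most negative were those of the sodium pump subunit gene Atp1b1 (1.19 against 100.4 FPKM, -5.53), Sbk1 (-4.85), N4bp3 (-4.56), H2-Oa (-4.11), Mrgpre (-3.97), Lbh (-3.96), the lymphotoxin gene Ltb (-3.87), Tmem163 (-3.82), Bcar3 (-3.77) and Fam117a (-3.72). With a 0 taken as a value, Il1b came first, followed by genes such as Cst3 and Rpl35 that were listed at 0 in the other libraries.

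Of 3421 genes above 0 in both libraries, 291 were at least 2-fold higher and 896 at least 2-fold lower with LPS, and counting error alone gave a median of 11 each. The split depends on scaling: of the genes at least 2-fold apart 24.5% were higher as deposited, and 45.8% after median-of-ratios scaling, which gave 491 higher and 580 lower and moved the median of all genes by 0.33, where upper-quartile scaling moved it by 0.37. With a listed 0 taken as a value, 2605 were higher and 1674 lower, and the cytokine, interferon, ribosomal protein and mast cell lists were the only ones of the 7 apart that stayed so. NRF2 targets had 1 of 4 members at least 2-fold higher and 0 lower, histones 0 of 3 and 2, and NK cell markers 0 of 1 and 1.

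**Figure D2:**
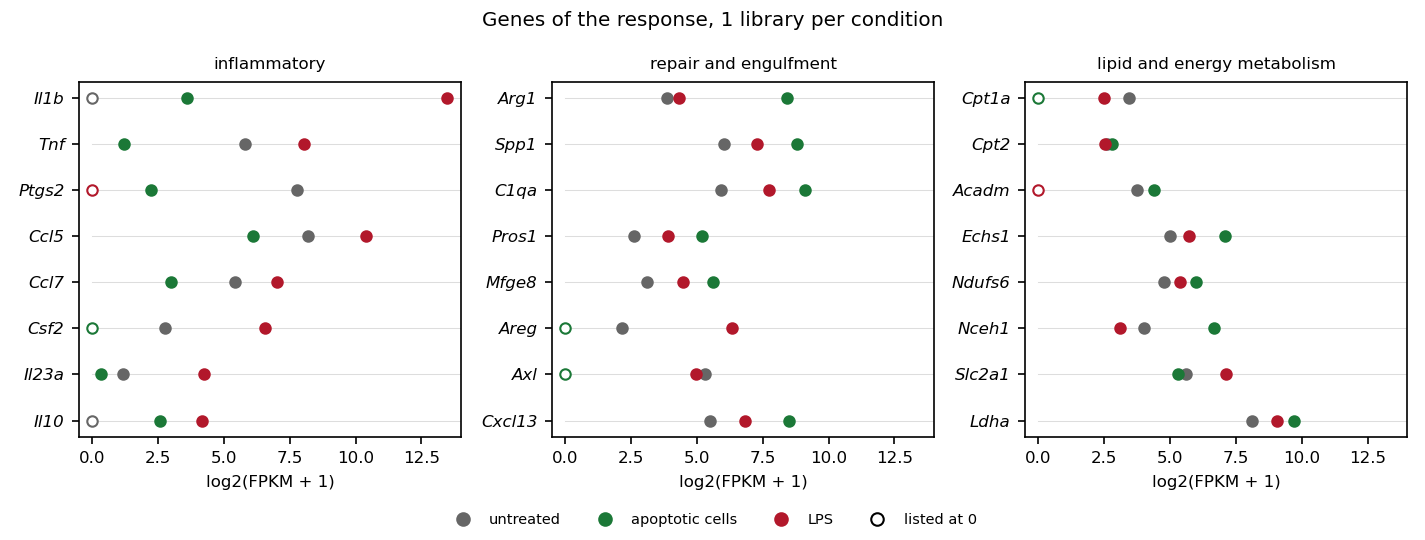
Level of 24 genes in the untreated (grey), apoptotic-cell (green) and LPS (red) libraries, as log2(FPKM + 1) on the horizontal axis, with 1 point per library and open points for values listed at 0. Il1b reaches 11441 FPKM with LPS, and Arg1 reaches 344 FPKM with apoptotic cells.

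The third comparison sets both stimuli against each other, without the untreated library. Il1b was at 11.2 FPKM with apoptotic cells and 11441 FPKM with LPS (log2 ratio -9.88), and Tnf at 1.30 and 264 FPKM (-6.85). Arg1 was higher with apoptotic cells, at 344 against 19.1 FPKM (4.10), as was Thbd, which encodes the anticoagulant thrombomodulin (58.1 against 2.03 FPKM, 4.29). F3, the tissue factor gene that starts clotting, was lower (1.32 against 65.3 FPKM, -4.84), as were Has1 (-5.31) and Phlda1 (-5.18). The median log2 ratio of all genes was 0.32.

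Complex I genes were higher with apoptotic cells than with LPS, with a median of 0.71 (interval 0.53 to 0.85, percentile 99.5), or 0.40 relative to all genes. Of 20 members 3 were at least 2-fold higher, Ndufv3 (47.8 against 19.2 FPKM), Ndufa13 (42.9 against 18.9 FPKM) and Ndufb11 (63.1 against 28.5 FPKM), 0 were lower and 17 differed by less. Over the members above 0 in all 3 libraries the percentile was 96.1, within the range of random lists. Fatty acid oxidation genes had a median of 0.68 (interval 0.14 to 1.64, percentile 96.7), or 0.37 relative to all genes. Of 14 members 5 were at least 2-fold higher with apoptotic cells, Hadh (12.1 against 2.93 FPKM), Acaa2 (8.80 against 1.98 FPKM), Decr1, Echs1 and Etfb, and 1 was lower, Acsl5 (47.9 against 118 FPKM). Medians were 0.38 for complexes II to IV (percentile 65.8), 0.60 for ATP synthase (92.6), 0.54 for the TCA cycle (89.1), 0.36 for glycolysis (59.7) and 0.27 for mitochondrial biogenesis and dynamics (44.1). The NAD and sirtuin list had a median of -0.25 (percentile 2.69). In it Sirt1 was listed at 11.0 FPKM with apoptotic cells, 8.31 FPKM with LPS and 0 in the untreated library, and Nampt, whose enzyme makes the NAD precursor, at 29.8, 0 and 0 FPKM.

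Cytokine genes had a median of -3.97 (interval -9.88 to 0.13, percentile 0), NF-kB targets of -2.09 (interval -4.33 to 0.75, percentile 0) and interferon-stimulated genes of -1.84 (interval -3.17 to -0.59, percentile 0), each with 6 members at least 2-fold lower with apoptotic cells and 0 higher. Relative to all genes these medians were -4.28, -2.40 and -2.16. Stress-response genes were lower as well (median -1.01, interval -2.61 to 0.61, percentile 0.02), with 5 of 10 members at least 2-fold lower, such as Chac1 (3.45 against 43.2 FPKM), Trib3 (11.4 against 74.6 FPKM) and Atf4 (64.8 against 240 FPKM), and Sdf2l1 higher. Immediate-early genes had a median of -0.48 (interval -0.99 to 0.69, percentile 0.03). Higher lists were alternative activation and repair (1.08, interval from -1.59 and spanning 0, percentile 99.8), engulfment (1.08, interval 0.11 to 2.82, percentile 99.7), lipid uptake and storage (1.10, interval -2.28 to 3.57, percentile 99.4), the lysosome (1.38, interval 0.40 to 3.48, percentile 99.8) and small peritoneal macrophage and monocyte markers (1.11, interval -1.09 to 3.23, percentile 99.4). With a listed 0 taken as a value, as planned, the cytokine, repair, engulfment, lipid uptake, lysosome and small peritoneal macrophage lists no longer stood apart. The immediate-early list did not over genes above 0 in all 3 libraries, the repair list with no filter, or the small peritoneal macrophage list with no filter or a pseudocount of 5. In the repair list 6 of 11 members were at least 2-fold higher, Arg1 and Clec10a (9.78 against 0.905 FPKM) foremost, and 3 were lower, Hbegf (-2.21), Il10 (-1.59) and Pdgfb (-1.53). Nceh1 was at 100.2 against 7.51 FPKM, and Atp6v0d2 at 19.2 against 0.811 FPKM. Medians were 0.52 for LXR targets (percentile 82.6), 0.63 for sterol synthesis (92.1), -0.08 for hypoxia (5.10), 0.42 for the cell cycle (66.1), 0.05 for antigen presentation (18.5), 0.31 for ribosomal proteins (47.2), 0.54 for housekeeping genes (87.8), 0.57 for B-cell markers (85.7) and 0.25 for mast cell markers (42.4). Lists added after the fixed markers had been seen stood apart, relative to all genes, further B-cell genes at 1.11 (4 of 7 at least 2-fold higher, 0 lower, percentile 99.9) and further macrophage genes at 2.11 (5 of 5 higher, percentile 100), with Cebpa at 206 against 26.0 FPKM.

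T cell and thymocyte markers were higher with apoptotic cells than with LPS in 8 of 8 members above 0 in both libraries, each by at least 2-fold (median 2.67, interval 1.23 to 4.65, percentile 100). Rag1 had the largest positive ratio of all ranked genes, at 41.2 against 0.679 FPKM (4.65), just ahead of Tmem37 (4.57). Dntt, the terminal transferase gene of immature lymphocytes, stood at 13.0 against 0.160 FPKM and Thy1 at 13.0 against 0.219 FPKM. Of 4599 genes above 0 in both libraries, 722 were at least 2-fold higher with apoptotic cells and 255 lower, where counting error alone gave medians of 14 and 13. Of the genes at least 2-fold apart 73.9% were higher as deposited and 51.9% after median-of-ratios scaling, which gave 440 higher and 407 lower and moved the median of all genes by -0.29, where upper-quartile scaling moved it by -0.13. With a listed 0 taken as a value the counts were 1741 and 1423, and the repair list turned from 1.08 to -0.14. NRF2 targets had 0 of 4 members at least 2-fold higher and 1 lower, histones 1 of 3 and 0, and NK cell markers 0 of 1 and 0.

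**Figure D3:**
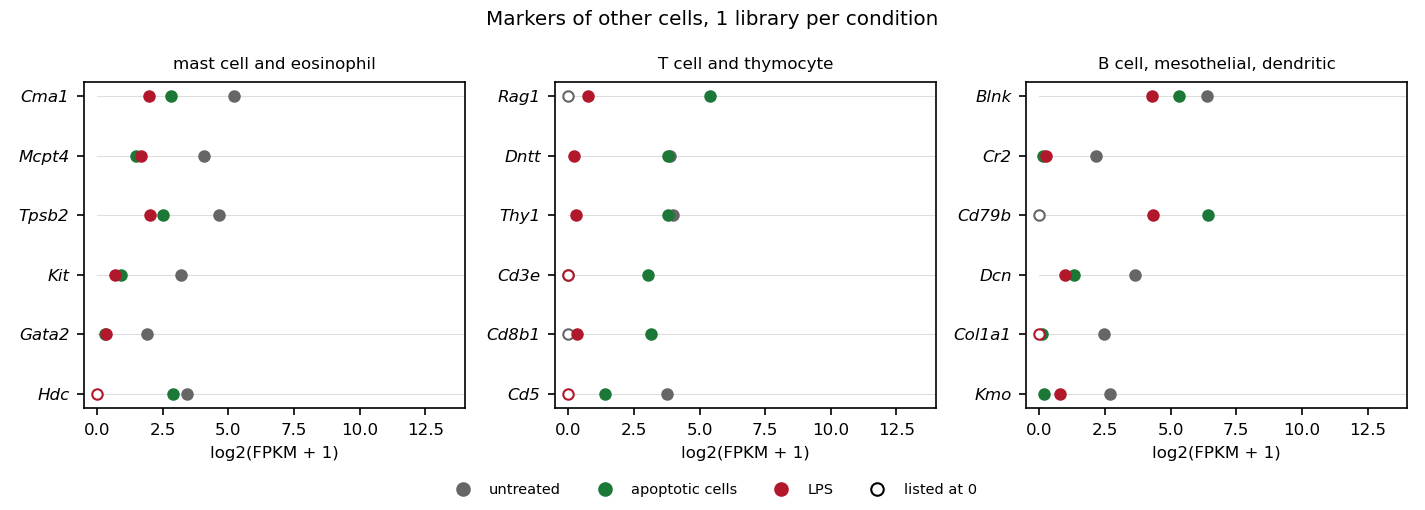
Level of 18 marker genes of other cell types in the untreated (grey), apoptotic-cell (green) and LPS (red) libraries, as log2(FPKM + 1) on the horizontal axis, with 1 point per library and open points for values listed at 0. Mast cell genes such as Tpsb2 (23.8, 4.72 and 2.99 FPKM) are highest in the untreated library, and Rag1 stands at 41.2 FPKM with apoptotic cells.

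The last comparison asks what both stimuli shared. Over 2891 genes above 0 in all 3 libraries, 101 were at least 2-fold higher with both and 347 at least 2-fold lower with both. The split depends on scaling: upper-quartile scaling gave 207 and 224, and median-of-ratios scaling gave 168 higher with both. Genes higher with both included Apoc1, the acute-phase gene Saa1 (3.02 with apoptotic cells, 2.75 with LPS), the platelet factor gene Pf4 (2.57 and 2.71), C5ar1 (3.15 and 2.34) and C1qa. Genes lower with both included Atp1b1, N4bp3, Bcar3, Ltb and the transcription factor gene Foxo1 (-2.85 and -3.63). Opposite responses were seen in 23 genes lower with apoptotic cells and higher with LPS, Tnf, Has1, Phlda1, Ch25h, Ccl5 and Ccl7 among them, and in 15 genes higher with apoptotic cells and lower with LPS, Thbd, Mmp8, the ecto-nucleotidase gene Nt5e (1.80 and -1.54) and the ketone-body enzyme gene Oxct1 among them.

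Independent lists of the same sizes would share 28.9 genes higher with both and 129 lower with both, and would hold 39.0 and 96.0 genes in the opposite classes. Unchanged libraries simulated against 1 shared control gave a median of 3 genes higher with both and 2 lower with both. The Pearson correlation of the log2 ratios across genes, which are not independent replicates, was 0.58, where the simulation gave 0.48. Their covariance was 0.65 against a simulated 0.036, a difference of 0.61. The untreated group has a single library that cannot be split, so part of the excess may come from that shared control, in which mast cell and mesothelial markers were also higher.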

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

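The plan took a listed 0 as a value, and the restriction to genes above 0 in both libraries that the reported values use was chosen after the values were seen, as was the setting with genes above 0 in all 3 libraries. The other settings were chosen in advance. With 1 library per condition no library was left out, and no symbol was repeated, so an alternative for repeated symbols was not run. Of 30 list placements outside the random range, 11 held under every alternative run: cytokines, ribosomal proteins and mast cell markers with apoptotic cells, cytokines, interferon-stimulated genes, ribosomal proteins and mast cell markers with LPS, and interferon-stimulated genes, NF-kB targets, stress-response genes and T-cell markers between the stimuli. Of the values of named single genes under the alternatives, 197 crossed 2-fold and 2766 did not. Of the medians of lists outside the random range 235 stayed the same, 15 moved and 2 reversed, and of those within it 380 stayed the same and 36 moved. Depth limits what differences of low genes can show. On 2 kb of transcript, counted after the length offset is taken off, 1 FPKM is 6.78, 6.35 and 5.88 reads in the untreated, apoptotic-cell and LPS libraries. The cause of the changes below was not tested, beyond what a stricter or looser threshold or a smaller gene set does by construction.

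Counts are given as higher and lower, for apoptotic cells against untreated, LPS against untreated and apoptotic cells against LPS, beside the values reported of 418 and 554, 291 and 896, and 722 and 255. They were 746 and 1021, 543 and 1461, and 1537 and 496 at 1.5-fold, and 96 and 143, 68 and 194, and 148 and 90 at 4-fold. With a pseudocount of 5 they were 235 and 228, 164 and 321, and 278 and 155. With 0 as a value they were 2682 and 1378, 2605 and 1674, and 1741 and 1423. A mean of at least 5 FPKM left 268 and 429 lower against untreated and 398 and 163 between the stimuli. Median-of-ratios scaling gave 491 and 580 with LPS and 440 and 407 between the stimuli, upper-quartile scaling gave 517 and 543 with LPS, and genes above 0 in all 3 libraries gave 464 higher between the stimuli. Genes higher with both stimuli, 101 as reported, were 152 with a pseudocount of 0.1, 53 with 5, 168 with median-of-ratios and 207 with upper-quartile scaling, and 1738 with 0 as a value. Genes lower with both, 347 as reported, were 125 with a pseudocount of 5, 152 at a mean of at least 5 FPKM, 224 with upper-quartile scaling and 842 with 0 as a value.

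List medians follow by setting. With 0 as a value, as planned, the NF-kB list with apoptotic cells reversed from -1.62 to 0.37 and the repair list between the stimuli from 1.08 to -0.14. In that setting the engulfment list with apoptotic cells moved to 0.36, the lysosome to 0.55, antigen presentation to -0.62, lipid uptake to 1.04 and T-cell markers to 2.63, at percentile 98.9. With LPS lipid uptake moved to 1.26, mitochondrial biogenesis to 0 and small peritoneal macrophage markers to 1.18.

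With a pseudocount of 0.1, mast cell markers with apoptotic cells were at -2.81, and the NF-kB and cell cycle lists with LPS at 1.78 and -1.58, the latter at percentile 1.95. With a pseudocount of 5, the cell cycle list was at -0.34, -0.44 and 0.21 in the 3 comparisons, and the NF-kB and mast cell lists with LPS at 0.71 and -1.38. With no filter, lipid uptake with LPS was at -0.43. Rescaling to a common sum put mast cell markers with apoptotic cells at -2.62, and the NF-kB and cell cycle lists with LPS at 1.72 and -1.53, the latter at percentile 2. In both of these settings the cell cycle list with LPS is thus below the random range, unlike the reported percentile of 8.08.

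Median-of-ratios scaling gave, with LPS, NF-kB 1.69, ribosomal proteins -0.63, complexes II to IV 0.51, arginine genes 0.73, lipid uptake 0.35, mitochondrial biogenesis -0.066 and the stress response 0.89. Between the stimuli it gave complex I 0.36 at percentile 99.6, complexes II to IV 0.033, ATP synthase 0.24, the TCA cycle 0.20, the cell cycle 0.21, ribosomal proteins -0.046 and sterol synthesis 0.29. Upper-quartile scaling gave, with apoptotic cells, complex I 0.89, ATP synthase 0.67, the TCA cycle 0.37 and ribosomal proteins -0.35. With LPS it gave NF-kB 1.71, ribosomal proteins -0.59, complexes II to IV 0.55, ATP synthase 0.16, arginine genes 0.77, housekeeping 0.41, lipid uptake 0.39, mitochondrial biogenesis -0.034 and the stress response 0.93. Between the stimuli it gave ATP synthase 0.44, the TCA cycle 0.39, ribosomal proteins 0.15 and sterol synthesis 0.48. A scaling factor shifts all ratios of a comparison together by construction.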

Other observations

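The tests of scaling and of a lower macrophage share on neutrophil markers, of further macrophage genes and of T-lineage markers were chosen after the results they address had been seen, and the tests of further B-cell, mesothelial and mast cell genes and of gene length were set for patterns already seen but before their own values were looked at. Arg1, the cytosolic arginase gene, stood at 344 FPKM with apoptotic cells, 13.7 in the untreated library and 19.1 with LPS, while Arg2, its mitochondrial relative, stood at 5.99, 6.94 and 66.8 FPKM. With apoptotic cells the arginine importer gene Slc7a1 (7.02 against 43.7 FPKM in the untreated library) and the polyamine enzyme gene Odc1 (22.7 against 75.7 FPKM) were lower, and Slc7a2, another importer gene, was listed at 37.6 FPKM and at 0 in both other libraries. The list of arginine, ornithine and polyamine genes had a median of 0.33 with LPS (percentile 84.6) and 0.45 between the stimuli (percentile 71.8), and too few members above 0 to be placed with apoptotic cells.

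Xist, the RNA that silences an X chromosome in female cells, was listed at 22.8 FPKM in the untreated library, 0.788 with apoptotic cells and 1.04 with LPS. The 4 Y-linked genes looked up after this was seen, Ddx3y, Eif2s3y, Kdm5d and Uty, were listed at 0 in all 3 libraries. No explanation was tested. The labels give no sex and do not say whether the 3 libraries come from the same animals, on which the meaning of every ratio to the untreated library depends.

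Mast cell and mesothelial markers were higher, and the macrophage genes Cxcl13 and Cd9 lower, in the untreated library than in both others, while neutrophil markers such as S100a8 and Lcn2 were also lower there. One scaling factor per library, and a lower share of macrophages as the whole cause, would move mast cell and neutrophil markers alike. With apoptotic cells the lowest neutrophil marker lay 0.59 above the upper end of the interval of the mast cell median. That marker, Camp, stood at 0.752 against 0.713 FPKM, where the added 1 FPKM holds a ratio near 0, so this gap cannot decide. In that comparison 3 of 5 neutrophil markers were at least 2-fold higher and 5 of 6 mast cell markers at least 2-fold lower. A single scaling factor alone cannot give both. A lower macrophage share as the whole cause stays open. A larger share of single cell types may account for part of the pattern and also stays open. With a pseudocount of 0.1 and no filter, further mesothelial and stromal genes lay -0.49 and -2.69 from all genes with apoptotic cells and LPS. Further mast cell genes lay -0.81 and -0.26 from all genes, where below -1 in both had been required of each list. On the scale and filter of the report the mesothelial and stromal genes lay -1.20 and -1.31 from all genes (percentiles 0.69 and 0.19). Further B-cell genes had as few as 0 members above 0 in both libraries and further macrophage genes 4, where 5 were needed; the macrophage genes lay 1.95 above all genes with apoptotic cells, while with LPS Pld4 (-3.14) was lower and Cebpa (-0.48), Tlr13 (-0.08) and Fcgr1 (0.30) were under 2-fold. A loss of these cells under both treatments, or expression of S100a8 and Lcn2 by the macrophages, was not tested.

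T-lineage transcripts were present with apoptotic cells, where 17 of 22 markers were above 0, against 8 in the untreated library and 13 with LPS, of which 4 passed 1 FPKM. RNA carried in by the apoptotic cells may be their source, although the labels do not say which cells these were. The 7 markers above 0 in both the apoptotic-cell and untreated libraries, Dntt and Thy1 among them, were not higher with apoptotic cells (median -0.35, interval -2.38 to -0.04, 0 of 7 higher). The untreated library also held more mast cell and mesothelial transcripts, so carried-in RNA, resident T cells and other sources cannot be told apart. Dntt, a gene of immature lymphocytes, stood at 13.5 FPKM in the untreated library, whose label names no apoptotic cells. Its source there was not tested. For the 10 markers listed at 0 in the untreated library, Rag1 among them, the 0 decides nothing, because 31.2% of the genes above 20 FPKM in both other libraries were listed at 0 there as well.

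Cytosolic ribosomal protein genes were higher in the untreated library than in either treated library. Gene length, which could enter through the FPKM scale, was tested only coarsely. Among random lists matched on level and on 3 classes of transcript length, the list stayed at percentile 0.07 with apoptotic cells and 0.04 with LPS. This argues against length at the scale of those classes. It cannot exclude an effect confined to the shortest transcripts within a class. Level was matched only in deciles, which can mix ribosomal protein genes with much less abundant ones. In level-matched random lists the ATP synthase genes, such as Atp5a1 (122 FPKM untreated), had the same medians, 0.39 and 0.20, as ribosomal genes, such as Rpl3 (878 FPKM). An effect confined to the most abundant genes therefore cannot be excluded either. A response to both treatments and a larger share of lymphoid cells in the untreated library stay open and were not tested on these genes.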
